A study of Oryza sativa with 8 samples.

How the data were processed

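Rice plants (Oryza sativa cv. Nipponbare) aged 2 weeks were grown at 28 °C with 14 h of light and 10 h of darkness a day, per the labels' protocols. The second leaf blade was wounded with a pin holder, and leaves were compared with untreated leaves 30, 60, 120 and 240 min later. Total RNA was isolated with an RNeasy plant kit and amplified and labelled with an Agilent kit for low RNA input, per the labels' protocols. Each of the 8 2-colour arrays held RNA of untreated leaves in Cy3 and of wounded leaves in Cy5, with 2 biological replicates at each time. No array had the dyes swapped, so a dye effect specific to a gene cannot be separated from its ratio. The time of day at which the untreated leaves were taken, and whether an untreated RNA served several arrays, are not given in the sources used here.

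The deposited scanner files hold spot intensities, namely the mean signal and the median local background in each channel, made with Agilent Feature Extraction 10.5.1.1, per the file headers. They also hold processed signal intensities that the software had background-subtracted and dye-normalized (linear and LOWESS), per the file headers, and their log10 ratio of Cy5 over Cy3. The authors' deposited value table holds log10 ratios. Set against the log10 ratio of the same array, each of its columns had a correlation of at least 0.999999 and a largest gap of 0.005, the size of rounding. Its scale and direction are therefore those of the scanner software, with no further centring. Its column medians were -0.00386 and -0.0145 for the 2 replicates at 30 min and 0 for the other 6 arrays.

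Ratios were recomputed from the mean signals with R 4.3.3 and limma 3.58.1. The background was corrected with normexp (offset 50), and each array was normalized by loess with control spots at weight 0. Of 45151 spots, 1417 control spots and 590 control spots of the array design were left out, as were spots with an outlier flag. Spots of a probe were averaged, which gave 42418 probes. Genes were named by the rice locus in the files' annotation, which can be old, and a locus with several probes (7801 of 29690 loci) was represented by its brightest probe. Among the named genes with other probes at a time, 236 in all, 3 had another probe of opposite sign: Os09g0255400 at 30 min, and ACX1 (Os06g0103500) and Os05g0583000 at 240 min. The reference table, of another assembly, holds neither these loci nor the array's accessions, so 0 names were taken from it and no coordinates are given. A spot had to be well above background in either channel on at least 2 of the 8 arrays, which removed 6578 features and left 23622 for testing (23491 loci and 131 features of microRNA probes). The number of spots well above background on an array lay between 30046 and 31478 in the untreated channel and between 31004 and 33312 in the wounded channel, and the small number of arrays limits the precision.

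The log2 ratios were fitted with lmFit and eBayes in limma, with a mean for each time and the spread shared by all 8 arrays (4 residual degrees of freedom). Each mean was tested against 0 and 4 differences between times were tested, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A test of a ratio against 0 holds the spread of the untreated leaves only as far as it lies between the 2 slides. Where a gene was not well above background on any array of a group in a channel, the fold is given as at least N-fold, from channel means after loess and Aquantile, with the dim channel of an array set to no less than the lowest signal well above background on that array. Those bounds are open to dye bias. Gene lists were written from product descriptions and known loci, 46 in all, and 35 had at least 5 tested genes. By a rule on the annotated product 7 known loci were left out, among them DREB1A, the clock gene PRR59 and the diterpenoid gene CPS2. These 35 were tested at 4 times with camera (preset correlation 0.01), with adjustment over 140 tests, and again with an estimated correlation. Camera used genes with a value on every array, which left out 1 member each of the heat shock (121 of 122 tested), ribosomal (154 of 155), peroxidase (67 of 68), protease inhibitor (42 of 43) and auxin lists (41 of 42), while counts and medians hold all tested members. The rule for named genes took the 8 largest increases and the 4 largest decreases at each time. It added up to 3 called members of each list at each time, the 4 largest changes in each direction of each difference, and 15 genes named whatever their result. The design, the lists, the rule and the alternatives were fixed before the data were examined, except centring on the spike-in controls, which was chosen after their ratios had been seen.

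Replicate 1 of all 4 times lay on a slide of its own with its own scan day, and so did replicate 2, so the number pairs the arrays. The differences between replicates correlated across genes between the times, with r from 0.541 to 0.766 for the 6 pairs of times. The 4 residual degrees of freedom come from these differences, all between the same 2 slides, and are not independent. The p against 0 may therefore be too small. The correlation of arrays of 1 slide estimated by limma was 0.420. Fits with the slide as a fixed and as a random block were alternatives. For a test against 0 the fixed block takes the mean difference between the slides out of the spread. That difference holds the spread between the untreated leaves of the slides, so p against 0 with this block leave it out. In a difference between times the mean difference between the slides cancels within a slide, a pairing that the main fit leaves unused.

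The other alternatives were no background subtraction, another normexp offset (16), the scanner software's processed signals, the deposited value table, median centring in place of loess, and scaling and Aquantile between arrays. Further alternatives were other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust estimation, an absolute log2 ratio of at least 1 in addition, and each array left out in turn. The calls were tested on simulated data with 23622 genes, of which 100 were changed by log2 1 and 100 by log2 2 in each comparison. At 30, 60, 120 and 240 min, 89, 89, 91 and 89 of the first and 96, 96, 97 and 97 of the second were recovered, with 9, 7, 5 and 15 false calls. A simulated list of 40 genes raised by 0.5 gave p = 5.54e-52 with the preset and 5.69e-05 with an estimated correlation, and an unchanged list gave 0.725 and 0.7. The simulated errors were independent between arrays and between genes. In the data the correlation was 0.420 for arrays of 1 slide and was estimated as 0.545 for ribosomal genes. The simulation therefore cannot show how often false calls arise under such correlation.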

Results

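The transcript levels of wounded rice leaves were measured against untreated leaves at 4 times on 8 2-colour arrays, 2 at each time, of which 23622 features were tested. All values are log2 ratios of wounded over untreated leaves, given as the mean ± SD of n = 2 replicates, with adjusted p from limma. The replicates of a time correlated across genes with r = 0.909, 0.923, 0.928 and 0.918 at 30, 60, 120 and 240 min, where genes are not independent replicates. Changes called largest are so among called genes with an informative description and the same sign in both replicates. The question is which genes respond to wounding, when they do so, and whether the response differs between the times. The untreated channels of a slide differed little between its arrays, with a spread of 0.139 to 0.189 across genes. That of the wounded channels was 0.641 to 1.14. The harvest time of the untreated leaves is not given, so for no gene below can wounding be separated from the time of day.

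At 30 min 7186 genes differed from untreated leaves, 4404 higher and 2782 lower. At 60 min 14032 differed (7401 higher, 6631 lower). At 120 min the count was 14761 (7554 higher, 7207 lower) and at 240 min 13378 (7045 higher, 6333 lower). Of these, 7182, 14029, 14755 and 13359 had the same sign in both replicates. Changes of at least 2-fold were fewer, with 1626 genes higher and 352 lower at 30 min and 2992 and 1709 at 60 min. They numbered 2385 and 2815 at 120 min, and 1779 and 1905 at 240 min. Increases of at least 8-fold numbered 244, 465, 242 and 142 in the order of the times, and such decreases 5, 62, 107 and 95.

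The balance of higher and lower genes depended on the scaling. With median centring the called genes were 72.1% higher at 30 min, 66.4% at 60 min, 67.6% at 120 min and 66.5% at 240 min, against 61.3%, 52.7%, 51.2% and 52.7% with loess. The scanner software's processed signals gave 41.7% higher at 30 min (3745 higher, 5239 lower), and the deposited values gave 41.7% (3744 and 5245). At 60 min they gave 43.9% (6445 and 8250) and 43.9% (6445 and 8245). With the ratios centred on the spike-in controls, chosen after they had been seen, 77.5% of the called genes were higher at 120 min (12907 and 3737) and 89.0% at 240 min (16253 and 2010). The median of all genes shifted to 0.16, 0.28 and 0.24 at 60, 120 and 240 min with median centring. It shifted to -0.12 and -0.10 at 30 and 60 min with the processed signals, to -0.12 at 30 min with the deposited values, and to 0.44 and 0.61 at 120 and 240 min with the spike-ins. All directions below are relative to the loess curve of each array.

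**Figure D1:**
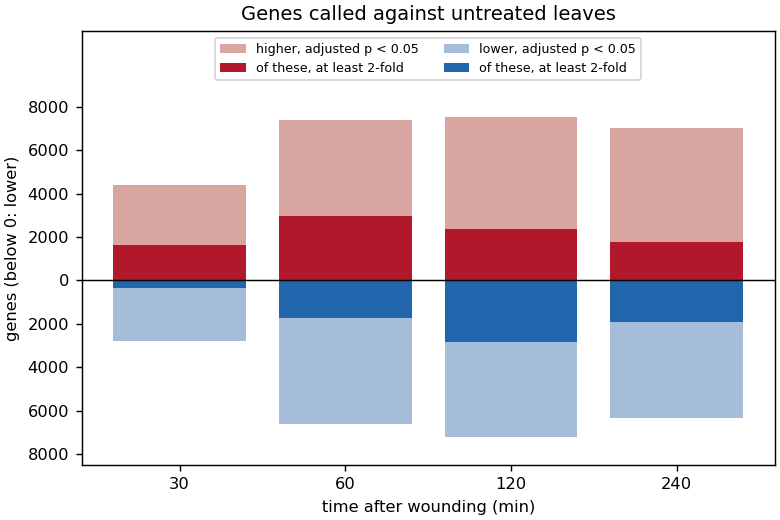
Number of genes called higher (above 0) and lower (below 0) in wounded than in untreated leaves at each time in minutes, from limma with 2 replicates per time. Dark bars are the called genes that changed at least 2-fold, from 1626 higher and 352 lower at 30 min to 2385 and 2815 at 120 min.

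At 30 min genes annotated as 12-oxophytodienoic acid reductases were among the largest increases, and parts of the jasmonate lists rose. OPR1 (Os06g0216300), with this annotation, rose by 6.36 ± 1.01 (SD, n = 2, adjusted p = 0.000667). Os06g0216200, with the same annotation, rose by 5.66 ± 0.889. The annotation does not show whether these reductases act in jasmonate synthesis. OPR7, another reductase gene of the jasmonate biosynthesis list, rose by 0.82 ± 0.138. Of 12 genes of jasmonate biosynthesis, 8 rose and 1 fell, as they did adjusted over the list alone (median 0.82, camera adjusted p = 0.0303, and adjusted p = 0.709 with an estimated correlation). The allene oxide synthases AOS1 and AOS2 rose by 2.77 ± 0.536 and 2.68 ± 0.0424, whereas the lipoxygenase gene LOX2 fell by 0.83 ± 0.129. Of 16 genes of JAZ proteins, repressors of jasmonate responses, 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 1.14, camera adjusted p = 0.000613, and adjusted p = 0.709 with an estimated correlation). JAZ9 rose by 4.07 ± 0.351, JAZ13 by 3.68 ± 0.565 and JAZ11 by 2.62 ± 0.0624, while JAZ8 stood at 0.89 ± 0.569 (adjusted p = 0.117, 0.00979 with the slide as a block and 0.00784 with scaling). Of 4 transcription factor genes linked to jasmonate, 3 rose, also adjusted over the list alone, with bHLH148 at 3.46 ± 0.490, RERJ1 at 2.66 ± 1.56 and JAMYB at 1.21 ± 0.650. The fourth, MYC2, a central activator of jasmonate responses, stood at 0.64 ± 0.924 (adjusted p = 0.318, and 0.00297 with the slide as a block).

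Genes of the WRKY, AP2/ERF, NAC and calcium sensor lists rose at 30 min. Of 61 WRKY genes, 30 rose and 1 fell (35 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 4.21e-07, and adjusted p = 0.709 with an estimated correlation). Among these genes were Os09g0417600 at 4.31 ± 0.707 and WRKY24 (Os01g0826400) at 4.02 ± 0.816. WRKY45, a regulator of salicylate-linked defence, rose by 1.22 ± 0.245. The DREB1 genes, activators of cold and drought responses, rose steeply, DREB1B by 5.31 ± 0.337, DREB1A by 4.60 ± 0.481 and DREB1C by 3.61 ± 0.122. Of the 25 genes of the AP2/ERF and DREB list, which holds DREB1B and DREB1C but not DREB1A, and also Os01g0705700, annotated as ICE1, 12 rose and 2 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.0477, and adjusted p = 0.743 with an estimated correlation). Of 47 NAC genes, 21 rose and 5 fell (23 and 6 adjusted over the list alone, camera adjusted p = 0.0423, and adjusted p = 0.709 with an estimated correlation). Of 96 MYB genes, 21 rose and 21 fell (24 and 21 adjusted over the list alone, median -0.022, a median that turned positive with median centring, camera adjusted p = 0.484, and 0.879 with an estimated correlation). Of 44 genes of calcium sensors, 23 rose and 1 fell (24 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.000176, and adjusted p = 0.709 with an estimated correlation). They included a calmodulin (Os01g0949500) at 3.29 ± 0.349. Of 51 genes of glutathione S-transferases, enzymes of detoxification, 22 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.709 with an estimated correlation). Its members included GSTU31 (Os10g0481300) at 4.43 ± 0.0478. Of 15 genes of LEA proteins and dehydrins, protective proteins of drying tissue, 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.848 with an estimated correlation).

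Genes of cell division and histones fell at 30 min. Of 49 genes of cell division and histones, 27 fell and 2 rose (29 and 2 adjusted over the list alone, median -0.54, camera adjusted p = 5.52e-09, and adjusted p = 0.848 with an estimated correlation). This list held histone H1 (Os04g0253000) at -2.65 ± 0.104 and histone H4 (Os09g0553100) at -1.78 ± 0.312. Of 155 genes of cytosolic ribosomal proteins, 23 fell and 2 rose (6 and 1 adjusted over the list alone, median -0.13, -0.21 on slide 1 and -0.063 on slide 2, camera adjusted p = 2.48e-06, and adjusted p = 0.848 with an estimated correlation), a median that turned positive with median centring (adjusted p = 0.345). The largest decrease was that of Os07g0684100, annotated as thioredoxin-like, at -3.45 ± 0.260. Other large increases were those of the zinc finger gene ZPT2-14 (Os03g0820300) at 6.19 ± 0.575, a cytochrome P450 (Os07g0635500) at 5.90 ± 0.835 and a regulator of gene silencing (Os01g0955100) at 5.64 ± 0.0347. The 30 min count was 3667 without replicate 1 and 3459 without replicate 2 of that time, and 11753 with scaling between arrays. Scaling moved the medians of jasmonate biosynthesis, JAZ, WRKY and cell division genes at 30 min to 1.30, 1.84, 1.21 and -0.91, and that of calcium sensors to 0.42, which was 0.45 with median centring. RERJ1 was not called without replicate 1 (1.56, adjusted p = 0.34) or 2 (3.77, adjusted p = 0.053). JAMYB was not called without replicate 1 of 30 min (0.75, adjusted p = 0.0531). The call of the NAC list ended with the slide as a block (adjusted p = 0.0628), median centring (0.285), scaling (0.106), no filter on dim probes (0.0994), no background subtraction (0.0521) and without replicate 1 (0.053) or 2 (0.0604) of 60 min. That of the AP2/ERF and DREB list ended with scaling (0.096), no filter (0.0866), the stricter filter on both channels (0.141) and without the same arrays (0.0638 and 0.0732). That of the LEA list ended with median centring (0.23) and no filter (0.115).

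At 60 min genes of the jasmonate biosynthesis list and of JAZ repressors lay above untreated leaves. OPR1 was 7.65 ± 1.17 above untreated leaves (SD, n = 2, adjusted p = 0.000106), AOS1 4.28 ± 0.332, JAR1, which joins jasmonic acid to isoleucine, 2.58 ± 0.115, the allene oxide cyclase gene AOC 2.28 ± 0.376 and OPR7 1.75 ± 0.336. Of the 12 genes of jasmonate biosynthesis 9 rose and 1, LOX2 at -2.02 ± 0.056, fell, also adjusted over the list alone (median 1.62, camera adjusted p = 0.021, and adjusted p = 0.709 with an estimated correlation). Of the 16 JAZ genes 11 rose and 0 fell, also adjusted over the list alone (median 1.98, camera adjusted p = 0.018, and adjusted p = 0.848 with an estimated correlation). Members of this list included JAZ11 at 4.33 ± 0.859 and JAZ8 at 2.32 ± 0.987. HPL3, a hydroperoxide lyase of green leaf volatile synthesis, fell by 1.59 ± 0.0239. RERJ1 stood at 0.69 ± 1.25 (adjusted p = 0.455, and 0.000541 with the slide as a block) and MYC2 at 0.78 ± 0.717 (adjusted p = 0.157, 0.000537 with the slide as a block and 0.0165 with median centring). Of 14 lipoxygenase genes 6 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.15 on slide 1 and 2.41 on slide 2, camera adjusted p = 0.15, 0.848 with an estimated correlation, 0.0199 with the slide as a block and 0.0468 without replicate 1 of 60 min). DREB1B and WRKY45 lay below untreated leaves, at -1.98 ± 0.012 and -2.53 ± 0.441.

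Genes of phenylpropanoids, glutathione S-transferases and pathogenesis-related proteins rose at 60 min. Of 40 genes of the phenylpropanoid pathway, which makes lignin precursors, 21 rose and 2 fell, also adjusted over the list alone (median 0.99, 0.54 on slide 1 and 1.31 on slide 2, camera adjusted p = 0.00965, and adjusted p = 0.848 with an estimated correlation). Among them cinnamate 4-hydroxylase (Os02g0467600) was at least 24.0-fold higher (adjusted p = 1.34e-05) and a cinnamyl alcohol dehydrogenase (Os01g0528800) rose by 4.10 ± 0.187. Of 40 genes of the shikimate and tryptophan pathway 21 rose and 6 fell (23 and 6 adjusted over the list alone, camera adjusted p = 0.0477, and adjusted p = 0.709 with an estimated correlation). Its gene for indole-3-glycerol phosphate synthase (Os09g0255400) stood at 4.24 ± 0.558. Of the 51 glutathione S-transferase genes 29 rose and 9 fell (29 and 10 adjusted over the list alone, median 0.60, camera adjusted p = 0.00354, and adjusted p = 0.709 with an estimated correlation). A glutathione S-transferase gene named by its annotation only, tau class protein 4 (Os10g0528300), rose by 6.87 ± 0.618. Of 86 genes of pathogenesis-related proteins 32 rose and 8 fell (28 and 8 adjusted over the list alone, camera adjusted p = 0.0477, and adjusted p = 0.848 with an estimated correlation). They included a thaumatin-like protein (Os03g0244200) at 5.23 ± 0.101 and a chitinase (Os02g0605900) at 4.56 ± 0.0876. Among all 23622 features 7401 rose and 6631 fell at 60 min. PR1b and PBZ1, markers of salicylate-linked defence, stood at -0.006 ± 0.650 (adjusted p = 0.993) and 0.80 ± 0.307 (adjusted p = 0.0884, 0.0101 with the slide as a block, 0.0141 with median centring, and 0.0192 without either array of 240 min).

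Parts of the lists of regulators lay above untreated leaves at 60 min. Of the 61 WRKY genes 30 rose and 9 fell (30 and 10 adjusted over the list alone, camera adjusted p = 0.0303, and adjusted p = 0.848 with an estimated correlation). Of the 25 genes of the AP2/ERF and DREB list 16 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 0.0303, and adjusted p = 0.709 with an estimated correlation). Its members included an ethylene-responsive coactivator (Os06g0592500) at 5.16 ± 0.404. Of the 44 genes of calcium sensors 25 rose and 7 fell (26 and 9 adjusted over the list alone, camera adjusted p = 0.0323, and adjusted p = 0.709 with an estimated correlation). Of the 155 ribosomal protein genes 61 rose and 9 fell (55 and 8 adjusted over the list alone, median 0.17, 0.66 with median centring and 0.060 with processed signals, camera adjusted p = 0.018, and adjusted p = 0.879 with an estimated correlation). Of 71 genes of the photosynthetic apparatus 27 fell and 8 rose (25 and 8 adjusted over the list alone, median -0.29, -0.091 with median centring, -0.12 on slide 1 and -0.40 on slide 2, camera adjusted p = 0.0477, and adjusted p = 0.848 with an estimated correlation). All 8 that rose encode proteins with a plastocyanin-like domain, a copper-binding domain also found in extracellular proteins outside photosynthesis. The largest decreases were those of a zinc finger gene (Os02g0148000) at -5.20 ± 0.413 and a CONSTANS-like gene (Os02g0731700) at -4.38 ± 0.489. Calls lost with median centring were those of jasmonate biosynthesis (adjusted p = 0.054), WRKY (0.0894), shikimate and tryptophan (0.0894), pathogenesis-related (0.2) and photosynthetic genes (0.134). With that centring the medians of jasmonate biosynthesis, WRKY, shikimate and pathogenesis-related genes were larger than with loess, at 2.15, 0.72, 0.57 and 0.38. The ribosomal call was lost with processed signals (0.207), the deposited values (0.212) and spike-in centring (0.0743), and the photosynthetic call with processed signals (0.258), the deposited values (0.254) and no background subtraction (0.0527). With no filter on dim probes the WRKY (0.0583), AP2/ERF and DREB (0.0583), pathogenesis-related (0.12), calcium sensor (0.0518) and photosynthetic calls (0.0866) ended. With the stricter filter on both channels the AP2/ERF and DREB (0.104) and pathogenesis-related calls (0.0622) ended. Without replicate 2 of 60 min the calls of the ribosomal (0.121), photosynthetic (0.174), pathogenesis-related (0.139) and shikimate lists (0.0617, and 0.0544 without replicate 2 of 240 min) were lost. Without replicate 1 of 60 min the same held for that of the AP2/ERF and DREB list (0.0542). Median centring moved the median of glutathione S-transferases at 60 min to 0.97. The WRKY and calcium sensor calls ended with scaling (0.0688 and 0.0722).

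**Figure D2:**
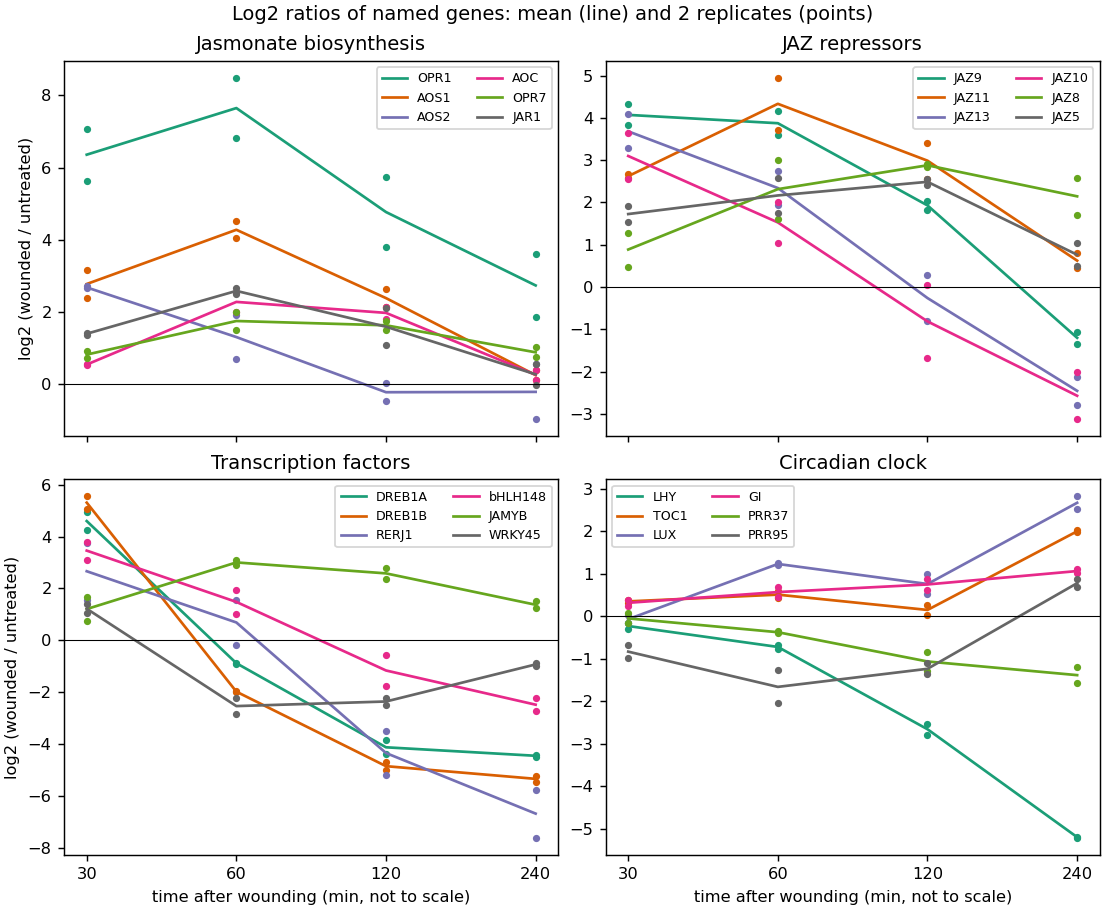
Log2 ratio of wounded over untreated leaves for named genes at each time in minutes (not to scale), with lines for the mean and points for the 2 replicates. OPR1 reached 7.65 at 60 min and DREB1B went from 5.31 at 30 min to -5.34 at 240 min.

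At 120 min transcripts of ribosomal proteins lay above and those of photosynthesis below untreated leaves. Of the 155 genes of cytosolic ribosomal proteins 151 rose and 1 fell, also adjusted over the list alone (median 1.04, 1.03 on slide 1 and 1.05 on slide 2, camera adjusted p = 2.74e-25, and adjusted p = 0.848 with an estimated correlation). This list held ribosomal protein S2 (Os07g0207400) at 2.07 ± 0.00917 and L34 (Os08g0156800) at 1.99 ± 0.00946 (SD, n = 2). Of the 71 photosynthetic genes 47 fell and 8 rose (49 and 8 adjusted over the list alone, median -1.18, -0.63 with median centring, -0.76 with spike-in centring, -0.94 on slide 1 and -1.40 on slide 2, camera adjusted p = 2.63e-05, and adjusted p = 0.848 with an estimated correlation). Split by description, after the values had been seen, 42 of the 46 members other than plastocyanin-like domain proteins fell and 0 rose (median -1.61), and of the 25 plastocyanin-like members 8 rose and 5 fell. The photosystem II 10 kDa protein gene (Os07g0147500) fell by 3.19 ± 0.571. Of 13 genes of chlorophyll biosynthesis 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.92, -0.28 with median centring and -0.50 with spike-in centring, camera adjusted p = 0.0168, and adjusted p = 0.848 with an estimated correlation). Members of this list included subunits of magnesium chelatase, which starts the chlorophyll branch, at -2.75 ± 0.558 (Os03g0323200) and -2.11 ± 0.545 (Os03g0563300).

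Heat shock and phenylpropanoid genes rose at 120 min. Of 122 genes of the heat shock list 67 rose and 21 fell (67 and 23 adjusted over the list alone, median 0.36, camera adjusted p = 0.00488, and adjusted p = 0.848 with an estimated correlation). Among these genes were small heat shock proteins (Os01g0184100 and Os02g0758000) at 6.20 ± 0.255 and 5.91 ± 0.185. Of its 51 members other than DnaJ family proteins and heat shock factors, a split made after the values had been seen, 35 rose and 5 fell (median 1.22). Of its 71 DnaJ family proteins and heat shock factors 32 rose and 16 fell (median 0.13). Of the 40 phenylpropanoid genes 24 rose and 2 fell (24 and 3 adjusted over the list alone, median 0.94, 0.52 on slide 1 and 1.15 on slide 2, camera adjusted p = 0.00635, and adjusted p = 0.848 with an estimated correlation). They included cinnamate 4-hydroxylase (Os02g0467600) at 4.42 ± 0.347. Of the 12 genes of jasmonate biosynthesis 8 rose and 1 fell, also adjusted over the list alone (median 1.67, camera adjusted p = 0.0477, and adjusted p = 0.709 with an estimated correlation). Its members included OPR1 at 4.77 ± 1.38 and AOC at 1.97 ± 0.230. Of the 16 JAZ genes 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.138, 0.0299 without replicate 2 of 120 min, and 0.848 with an estimated correlation). This list held JAZ11 at 2.99 ± 0.599 and JAZ8 at 2.88 ± 0.0558. RERJ1 and the DREB1 genes lay below untreated leaves, RERJ1 at -4.34 ± 1.21, DREB1B at -4.85 ± 0.231 and DREB1A at -4.12 ± 0.381.

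The largest increases at 120 min were those of a flavin-containing monooxygenase (Os04g0223500) at 7.16 ± 0.209 and a dioxygenase annotated as RAMOSUS1 (Os01g0566500), a carotenoid-cleaving enzyme of strigolactone synthesis, at 6.55 ± 0.0328. The linalool synthase gene LIS rose by 5.69 ± 2.29 (adjusted p = 0.0194). The largest decrease was that of a Myb gene (Os05g0579600) at -5.48 ± 0.0714. With median centring the medians of ribosomal, phenylpropanoid and heat shock genes at 120 min were 1.90, 1.59 and 0.87, and that of heat shock genes was 0.78 with spike-in centring. LIS was not called without replicate 2 of 120 min (4.08, adjusted p = 0.195), and the chlorophyll call ended with median centring (adjusted p = 0.144). The median of jasmonate biosynthesis at 120 min was larger with median centring (2.5) and with spike-in centring (2.09). The call of jasmonate biosynthesis ended with median centring (0.24), spike-in centring (0.202), no background subtraction (0.0547), a normexp offset of 16 (0.0531), processed signals (0.0596), the deposited values (0.0571) and no filter on dim probes (0.0534). It also ended without replicate 1 of 120 min (0.0505), replicate 2 of 60 min (0.0536) or replicate 2 of 240 min (0.051).

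At 240 min ribosomal protein genes lay above untreated leaves, and RERJ1 and the DREB1 genes lay below them. Of the 155 ribosomal protein genes 130 rose and 3 fell (134 and 3 adjusted over the list alone, median 0.47, camera adjusted p = 3.66e-13, and adjusted p = 0.848 with an estimated correlation). Of the 49 genes of cell division and histones 27 rose and 9 fell (29 and 9 adjusted over the list alone, median 0.46, 0.30 on slide 1 and 0.60 on slide 2, camera adjusted p = 0.0249, and adjusted p = 0.848 with an estimated correlation). Members of this list included histone H2B (Os01g0149600) at 1.65 ± 0.322 (SD, n = 2). RERJ1 stood at -6.68 ± 1.31, DREB1B at -5.34 ± 0.161 and DREB1A at -4.45 ± 0.0403, and DREB1C was at least 3.74-fold lower (adjusted p = 3.13e-05). JAMYB stood at 1.37 ± 0.200, a call that ended with scaling (1.27, adjusted p = 0.0544). Of the 4 transcription factor genes linked to jasmonate 1 rose and 2 fell (1 and 3 adjusted over the list alone). Of the 61 WRKY genes 14 rose and 21 fell (14 and 21 adjusted over the list alone, median -0.30, a median that turned positive with spike-in centring, camera adjusted p = 0.322, and 0.848 with an estimated correlation). Of the 16 JAZ genes 2 rose and 8 fell, also adjusted over the list alone (median -0.20, -0.86 with processed signals and -0.39 with median centring, a median that turned positive with spike-in centring, at 0.39 and still below the 0.61 of all genes, camera adjusted p = 0.331 and 0.0296 with that last centring, and 0.848 with an estimated correlation). Among these genes were JAZ13 at -2.46 ± 0.476, JAZ9 at -1.20 ± 0.211 (not called with scaling, adjusted p = 0.122), JAZ8 at 2.15 ± 0.619 and JAZ11 at 0.62 ± 0.262 (adjusted p = 0.124, 0.0291 with the slide as a block, 0.0109 with median centring, 0.0135 with spike-in centring, and 0.047 without either array of 60 min). MYC2 stood at -1.18 ± 0.500 (adjusted p = 0.053, 9.1e-05 with the slide as a block, and from 0.0432 to 0.0442 without either array of 30 or 120 min). Of the 12 genes of jasmonate biosynthesis 5 rose and 1 fell, also adjusted over the list alone (median 0.50, camera adjusted p = 0.331, and 0.848 with an estimated correlation). They included OPR7 at 0.88 ± 0.191 and LOX2 at -2.56 ± 0.363, while AOC stood at 0.26 ± 0.194 (adjusted p = 0.172, 0.0455 with the slide as a block, 0.00306 with median centring and 0.0065 with spike-in centring).

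Peroxidase, phenylpropanoid and heat shock genes rose at 240 min. Of 68 genes of the peroxidase list, mostly enzymes that cross-link lignin among other substrates, with 1 member (Os12g0448900) annotated as an animal haem peroxidase, 31 rose and 11 fell, also adjusted over the list alone (median 0.26, camera adjusted p = 0.0168, and adjusted p = 0.848 with an estimated correlation). Its members included a peroxidase (Os06g0547400) at least 25.6-fold higher (adjusted p = 4.97e-05). Of the 40 phenylpropanoid genes 20 rose and 3 fell, also adjusted over the list alone (median 0.88, 0.57 on slide 1 and 1.06 on slide 2, camera adjusted p = 0.0168, and adjusted p = 0.848 with an estimated correlation). This list held a phenylalanine ammonia-lyase (Os05g0427400), the entry enzyme, at 2.65 ± 0.324. Of the 122 heat shock genes 59 rose and 23 fell, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0168, and adjusted p = 0.848 with an estimated correlation). By the split made after the values had been seen, 23 of its 71 DnaJ family proteins and heat shock factors rose and 19 fell (median -0.009). Of its other 51 members 36 rose and 4 fell (median 0.94). Of 43 protease inhibitor genes, a class of proteins that blocks digestion in feeding insects, 15 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0769, 0.863 with an estimated correlation, 0.0199 with the slide as a block, 0.0437 with processed signals, 0.0431 with the deposited values and 0.0153 without replicate 1 of 240 min). Members of this list included an inhibitor of the Pin2 family (Os03g0734300) at 4.29 ± 0.346. Among all 23622 features 7045 rose and 6333 fell at 240 min. Of the 86 genes of pathogenesis-related proteins 32 rose and 17 fell, also adjusted over the list alone (median 0.32, 0.10 on slide 1 and 0.35 on slide 2, and 0.91 with spike-in centring, camera adjusted p = 0.186, and 0.848 with an estimated correlation). The pathogenesis-related gene JIOsPR10, known as jasmonate-inducible, rose by 4.84 ± 0.712 and PBZ1 by 1.03 ± 1.06 (adjusted p = 0.0414), while PR1b stood at -0.61 ± 1.14 (adjusted p = 0.339). The PBZ1 call ended without replicate 2 of 240 min (0.29, adjusted p = 0.496) and without either array of 30 min (0.0656 for both) or 60 min (0.0575 and 0.0574), as it did with processed signals and with the deposited values (0.0649 for both).

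Of the 13 genes of chlorophyll biosynthesis 9 fell and 2 rose at 240 min, also adjusted over the list alone (median -0.66, -0.066 with median centring and -0.066 with spike-in centring, camera adjusted p = 0.0473, and adjusted p = 0.848 with an estimated correlation). Of the 71 photosynthetic genes 29 fell and 12 rose, also adjusted over the list alone (median -0.30, -0.18 on slide 1 and -0.47 on slide 2, a median that turned positive with median centring and with spike-in centring, at 0.29 with the latter and still below the 0.61 of all genes, camera adjusted p = 0.0866, from 0.0317 to 0.0436 without replicate 1 or 2 of 120 min or replicate 1 of 240 min, 0.0398 with scaling, 0.00428 with spike-in centring, and 0.848 with an estimated correlation). The largest increases were those of the RAMOSUS1 dioxygenase (Os01g0566500) at 6.64 ± 0.244 and a chemocyanin precursor (Os03g0850900) at 6.07 ± 0.133. Among the largest decreases were a Dof zinc finger gene (Os01g0264000) at -5.26 ± 0.0493 and the clock gene LHY at -5.20 ± 0.0165. The 240 min count was 8112 without replicate 2 of that time, without which the calls of chlorophyll (adjusted p = 0.0945, and 0.0567 without replicate 2 of 60 min) and cell division genes (0.0899) ended. With median centring the calls of peroxidase (0.97), cell division (0.0721) and chlorophyll genes (0.39) ended. The chlorophyll call also ended with processed signals (0.0588), the deposited values (0.0561) and the stricter filter on both channels (0.0751), and the peroxidase call with no filter (0.176) and the stricter filter (0.0622). Spike-in centring ended those of peroxidase (0.241), phenylpropanoid (0.208) and cell division genes (0.254). The medians of ribosomal, cell division, heat shock, peroxidase and jasmonate biosynthesis genes at 240 min were 1.06, 0.93, 0.63, 0.090 and 1.1 with median centring and 1.06, 1.05, 0.84, 0.85 and 1.09 with spike-in centring. The phenylpropanoid median was 1.47 with spike-in centring, and the peroxidase median 0.71 with processed signals.

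**Figure D3:**
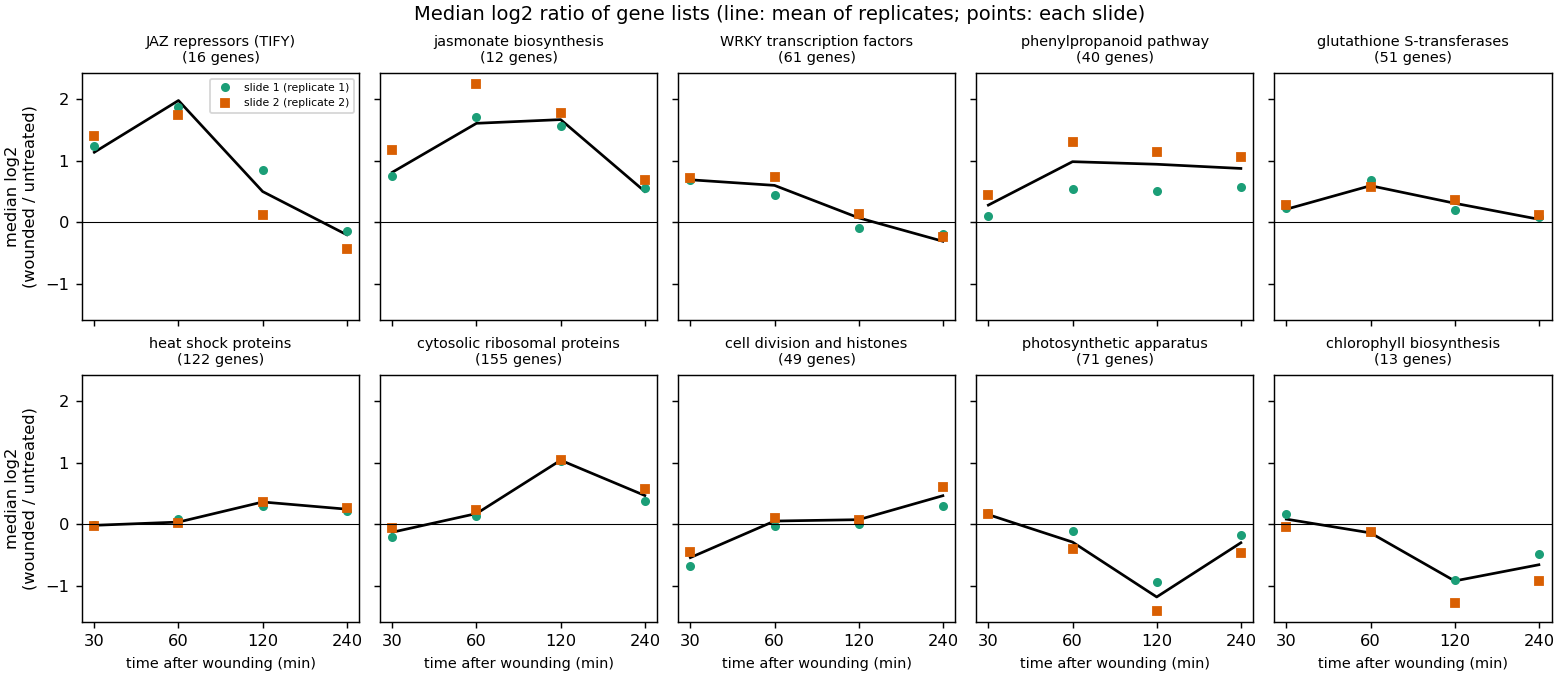
Median log2 ratio of wounded over untreated leaves for 10 gene lists at each time in minutes (not to scale), with the line for the mean of replicates and points for each slide. With median centring the ribosomal median at 30 min, the heat shock median at 30 min, the chlorophyll median at 60 min and the photosynthetic median at 240 min turned positive, as did the JAZ, WRKY and photosynthetic medians at 240 min with spike-in centring, while the heat shock median at 60 min and the chlorophyll median at 30 min turned negative with processed signals.

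Genes of the circadian clock moved apart with time. LHY, expressed in the morning in plants, stood at -0.23 ± 0.114 at 30 min (SD, n = 2, adjusted p = 0.0942, 0.0241 with the slide as a block and 0.0343 with processed signals) and fell by 0.72 ± 0.0727 at 60 min (not called with median centring, adjusted p = 0.0638). It stood at -2.66 ± 0.187 at 120 min and at -5.20 ± 0.0165 at 240 min. TOC1 and LUX, expressed towards the evening, rose by 1.99 ± 0.0327 and 2.66 ± 0.211 at 240 min, and GI rose by 1.06 ± 0.0795. PRR37 and PRR73 stood at -1.39 ± 0.264 and -1.23 ± 0.247 at 240 min. Of the 7 clock genes 4 were higher and 3 lower at 240 min, also adjusted over the list alone. The list as a whole was not called at that time (camera adjusted p = 0.821, and 0.939 with an estimated correlation). The untreated channel of these genes changed by a median absolute value of 0.13 between the 30 and 240 min arrays of a slide and the wounded channel by 1.64. An effect of wounding on these genes cannot be separated from the time of day, as the harvest time of the untreated leaves is not given in the sources used here.

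**Figure D4:**
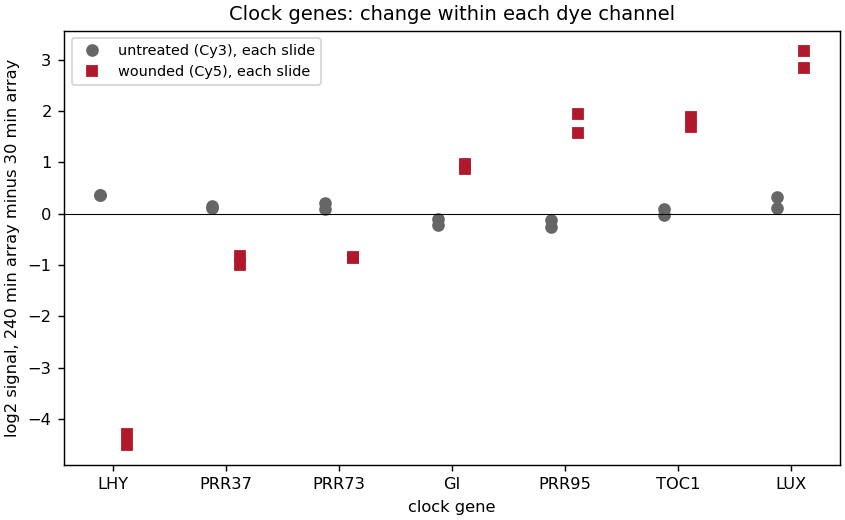
Change of the log2 signal of 7 clock genes from the 30 min to the 240 min array of a slide, in the untreated channel (circles) and the wounded channel (squares), 1 point for each of 2 slides. The wounded channel of LHY changed by -4.51 and -4.30 and the untreated channel by 0.365 and 0.364.

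The log2 ratios differed between times for many genes. For none of these genes can wounding be separated from the time of day, as the harvest time of the untreated leaves is not given. Between 30 and 60 min 8676 genes differed (4296 up, 4380 down), and between 60 and 120 min 9919 (4281 up, 5638 down). Between 120 and 240 min the count was 7283 (3753 up, 3530 down) and between 30 and 240 min 12000 (5686 up, 6314 down). This fit does not pair the arrays of a slide. With the slide as a fixed block 12420, 13464, 11257 and 15195 genes differed in the same order. As a random term it gave 11989, 12999, 10794 and 14924. DREB1B changed from 30 to 240 min by -10.64 ± 0.192 (SE, adjusted p = 3.43e-06), and Os08g0474000, annotated as RAP2.6, changed by -9.01 ± 0.734 (SE). From 120 to 240 min the early light-inducible protein genes Os07g0178700 and Os07g0178800 rose by 4.97 ± 0.331 and 4.25 ± 0.262 (SE), and the tau class protein 4 gene (Os10g0528300) fell by 4.03 ± 0.449 (SE), a call that ended with scaling (-3.14, adjusted p = 0.0713). The ribosomal list rose from 60 to 120 min in 145 of 155 genes and fell in 1 (camera adjusted p = 6.32e-33, and adjusted p = 0.837 with an estimated correlation). From 120 to 240 min 123 fell and 1 rose (3.31e-23, and adjusted p = 0.892 with an estimated correlation). The photosynthetic list fell in 32 and rose in 6 of 71 genes from 60 to 120 min (camera adjusted p = 0.00905, and adjusted p = 0.94 with an estimated correlation). It rose in 35 and fell in 5 from 120 to 240 min (0.000128, and adjusted p = 0.892 with an estimated correlation). The JAZ list fell from 30 to 240 min in 11 of 16 genes and rose in 0 (camera adjusted p = 0.00861, and adjusted p = 0.822 with an estimated correlation).

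These differences also depended on the scaling. With median centring 61.3%, 60.0%, 39.0% and 60.4% of the called differences were increases between 30 and 60, 60 and 120, 120 and 240, and 30 and 240 min, against 49.5%, 43.2%, 51.5% and 47.4% with loess. The count between 30 and 60 min was 5307 without replicate 1 and 5486 without replicate 2 of 30 min and 5733 without replicate 2 of 60 min. Between 120 and 240 min it was 3752 with scaling, 3676 without replicate 1 and 4560 without replicate 2 of 240 min, and 4439 without replicate 2 of 120 min. Between 60 and 120 min the share of increases was 55.7% with processed signals and with the deposited values and 76.7% with the spike-ins. Between 120 and 240 min it was 61.6% with scaling, 77.5% with the spike-ins and 49.8% with processed signals and with the deposited values. Between 30 and 240 min it was 83.5% with the spike-ins, 56.0% with processed signals (6813 and 5362) and 56.1% with the deposited values (6829 and 5340).

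By an F test over the 4 times 19415 genes differed from untreated leaves at some time. Of the 8557 of these with a change of at least 2-fold, 914 changed most at 30 min (782 up, 132 down), 2984 at 60 min (2021 up, 963 down), 2999 at 120 min (1215 up, 1784 down) and 1660 at 240 min (860 up, 800 down). Scaling between arrays moved the counts at 30, 60 and 120 min to 2846, 1950 and 1562, which reverses their order. Those at 30 and 240 min were 1525 and 2571 with processed signals and 1525 and 2568 with the deposited values, and that at 240 min was 3573 with spike-in centring. Of the 4404 genes higher at 30 min, 3066 were lower at 240 min than at 30 min and 1379 lay below untreated leaves at 240 min. Among all 23622 features 6314 were lower at 240 than at 30 min and 6333 lay below untreated leaves at 240 min. A choice of genes by high 30 min values itself favours a lower value at 240 min. Of 140 tests of a list at a time 33 were called with the preset correlation, 27 up and 6 down. With an estimated correlation 0 were called, where the smallest adjusted p was 0.709 and 9 had an unadjusted p under 0.05. In the simulated data that setting also raised the camera p of a list of uncorrelated genes, from 5.54e-52 to 5.69e-05.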

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

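The tests of the clock genes on each slide and of an effect of wounding on them, and those of random error in the spike-ins and of a larger share of rice transcripts, were chosen only after the result was seen. The other tests below were written before. Groups of 2 arrays are too small for a test of single arrays or of other splits of the samples.

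Differences between times drew attention to named genes that were called in opposite directions at 30 and 240 min. From 30 to 240 min the log2 ratio changed by -10.64 for DREB1B, -9.04 for DREB1A, -5.64 for DREB1C, -9.34 for RERJ1, -5.94 for bHLH148 and -2.15 for WRKY45, by -6.14 for JAZ13, -5.67 for JAZ10, -5.27 for JAZ9 and -3.97 for JAZ6, and by 1.61 for the clock gene PRR95. A called difference was part of the rule that chose these genes, so the calls of the differences are no further support. The change of DREB1C is no measured size, since its wounded signal was not well above background at 240 min, where it is given only as at least 3.74-fold lower. The opposite calls of RERJ1 rest on both arrays of 30 min, since its 30 min call ended without replicate 1 (1.56, adjusted p = 0.34) or replicate 2 (3.77, adjusted p = 0.053). Of the others, PRR95 was not called at 30 min without replicate 1 (-0.69, adjusted p = 0.165) or 2 (-0.98, 0.0729) of that time or with median centring (-0.55, 0.0518). JAZ10 was not called at 30 min without replicate 1 of that time (2.56, adjusted p = 0.0635) or at 240 min without replicate 2 of that time (-2.01, 0.068). At 240 min WRKY45 was not called with median centring (-0.29, adjusted p = 0.0796) nor JAZ9 with scaling (-1.11, 0.122). Across all genes 8676 differed between 30 and 60 min, 9919 between 60 and 120 min, 7283 between 120 and 240 min and 12000 between 30 and 240 min. Arrays left out moved the first of these to between 5307 and 8637 and the third to between 3676 and 6865.

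Genes induced early lay below untreated leaves later. Of 244 genes at least 8-fold higher at 30 min, 238 were lower at 240 min than at 30 min, and 114 were called lower than in untreated leaves at 240 min, against 60 called higher. The choice of these genes by their 30 min values itself favours a fall from 30 min. Noise of dim signals is argued against, since 106 of the 218 well above background in both channels on all arrays (48.6%) were lower, against a median of 33.5% (from 27.5% to 39.9%) in 10000 sets matched for brightness. Untreated leaves that already held part of the early response may be a source, which the values neither show nor exclude. The untreated levels of these genes differed between the slides by a median absolute value of 0.37, against 0.22 (from 0.19 to 0.26) in matched sets. Of 10000 sets 0 reached that value. The signed median, slide 2 minus slide 1, was only 0.075. The sets were matched for brightness and not for variability, so the difference cannot show that untreated leaves held the response. A fall of wounded leaves below their starting level cannot be told apart from a response held by untreated leaves. No untreated leaves of a known time stand beside the 240 min median of -0.48.

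Clock genes lay far from their untreated level at 240 min. Values of a single slide are argued against, since the median absolute log2 ratio of all 7 tested clock genes at 240 min was 1.20 on slide 1 and 1.57 on slide 2. In 10000 random sets of 7 genes it had a median of 0.34 and 0.41 and an upper percentile bound of 0.86 and 0.98 on these slides. Untreated leaves taken once for each slide, and not at each time, may account for the pattern, since the untreated level of these genes changed by a median of 0.13 between the 30 and 240 min arrays of a slide and the wounded level by 1.64. An effect of wounding on the clock cannot be told apart from the time of day, because the change of LHY by -4.96 has no untreated leaves of the same time to be set against.

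Spike-in controls, which no comparison uses, fell with time. The mean log2 ratio of 10 spike-in transcripts was 0.02 ± 0.188 at 30 min, -0.004 ± 0.150 at 60 min, -0.42 ± 0.114 at 120 min and -0.59 ± 0.0945 at 240 min (SD, n = 2), a change of -0.61 from 30 to 240 min, with -0.68 on slide 1 and -0.54 on slide 2. Random error in adding them is argued against, since the change is 4.33 standard errors made from the spread between arrays of a time, although that spread rests on 2 arrays each. With median centring the means were 0.39 and 0.17 on the 2 slides at 120 min, no lower than the 0.30 and 0.17 at 30 min. The fall from 30 to 120 min was thus absent with that centring. From the 60 min means of 0.47 and 0.36 they still fell to 120 min on both slides. For the fall at 240 min the loess normalization and a larger share of rice transcripts in the labelled RNA of wounded leaves cannot be told apart, since the change was -0.29 with median centring and the median of all genes was 0.61 at 240 min with the ratios centred on the spike-ins. Also unused by the comparisons, at most 15 spots of random control probes were well above background in Cy5 on an array and 10 in Cy3, where 240 such spots were read on each array.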

How the results depend on the processing

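Centring on the spike-ins was the alternative chosen only after the result was seen. A required log2 ratio of at least 1 left 1978, 4701, 5200 and 3684 genes at 30, 60, 120 and 240 min, with 3263, 3349, 2068 and 4912 for the differences of 60 and 30, 120 and 60, 240 and 120, and 240 and 30 min, and 8557 for the F test, a drop that the added requirement makes by construction. Scaling between arrays gave 11753 genes at 30 min and 3752 between 120 and 240 min, and moved the genes with their largest change at 30, 60 and 120 min to 2846, 1950 and 1562. Those at 30 and 240 min were 1525 and 2571 with processed signals and 1525 and 2568 with the deposited table, and 3573 at 240 min with the spike-ins. With an estimated correlation 0 lists were called. That correlation was 0.545 for ribosomal genes, but -0.0758 for jasmonate biosynthesis and 0.00332 for calcium sensors, below the preset 0.01. Even so, the unadjusted camera p of jasmonate biosynthesis at 30 min rose from 0.00522 to 0.0423. That of calcium sensors rose from 8.8e-06 to 0.00764. A larger correlation between genes is thus argued against as the cause for jasmonate biosynthesis and calcium sensors. For the simulated list of uncorrelated genes the camera p likewise rose from 5.54e-52 to 5.69e-05. The estimated setting can thus weaken a call without correlation between genes, so the loss of the list calls does not by itself show such correlation. What raised p in the data was not tested. Changes of sign in named results called in neither the main fit nor the alternative were not counted as reversals. Among the other named results directions reversed, without a call in the alternative, only for these small decreases: with median centring for Os03g0352300 at 60 min (0.072), Os11g0610600 at 120 and 240 min (0.14 and 0.12), Os03g0645900 at 240 min (0.085) and Os06g0142000 at 240 min (0.030), and with the spike-ins at 240 min for Os03g0645900 (0.19), Os11g0610600 (0.12), Os12g0596200 (0.20) and Os06g0142000 (0.11).

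With the slide as a fixed replicate block, more genes were called in every comparison: 10642, 16729, 17039 and 16068 at 30, 60, 120 and 240 min, 12420, 13464, 11257 and 15195 for the differences in the order above, and 21465 by the F test. As a random term it gave 7396, 14365, 15024 and 13635 at the times, 11989, 12999, 10794 and 14924 for the differences, and 20096 by the F test. Among 550 named results the block added 10 calls and ended 0, and among 140 list tests it added 3 and ended 1, each given in the report or here, which leaves PBZ1 at 120 min (adjusted p = 0.0122) and the phenylpropanoid list at 30 min (0.0196). For ratios against 0 the fixed block leaves the mean difference between slides, and with it the spread of the untreated leaves, out of the error. The block changed no other call among these named results and lists. As a random term it added 1 call among the named results, that of MYC2 at 240 min (0.0109).

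Leaving out an array gave 3459 to 6981 genes at 30 min, 10032 to 13999 at 60 min, 11259 to 14711 at 120 min and 8112 to 13296 at 240 min. The differences gave 5307 to 8637, 7343 to 9271, 3676 to 6865 and 8231 to 11977 in the order above, the F test 17981 to 18886 and the lists 25 to 36 calls. The genes with their largest change at 30, 60, 120 and 240 min numbered 904 to 984, 2797 to 3439, 2563 to 3657 and 1511 to 1988. The single array left at a time is taken to vary like the others. With camera set to an estimated correlation all 33 list calls ended. Over the other alternatives, each as far as it was run, 12264 named results kept their side of the threshold, 259 lost and 36 gained a call, and 9 reversed. The 12264 include changes of sign in results called in neither fit. Of the list results 2688 kept their side of the threshold, 66 lost and 46 gained a call. The 2688 include lists called in neither fit whose direction changed. A list's direction here is that of camera, relative to the other genes, and its median can change sign without it. The lists were not run with the slide as a random term, with trend and robust estimation or with the required log2 ratio. Aquantile leaves the ratios as they are and tests nothing. Signals near background limit the folds given as at least a value.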

Other observations

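The values on untreated leaves below were chosen only after the result was seen.

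Groups outside the called lists held single genes with large changes. An ACC oxidase (Os05g0149400), which makes ethylene, rose at 60, 120 and 240 min to 2.33, 2.79 and 3.17. Its list of 12 genes of ethylene biosynthesis was not called, with 3 higher and 5 lower at 60 min (3 and 6 adjusted over the list alone), 3 and 6 at 120 min and 3 and 4 at 240 min, the last 2 also adjusted over the list alone. Its camera adjusted p was 0.51, 0.51 and 0.995, and 0.848, 0.848 and 0.995 with an estimated correlation. Of 11 genes of diterpenoid phytoalexin biosynthesis 4 rose and 0 fell at 120 min (3 and 0 adjusted over the list alone, camera adjusted p = 0.136, and adjusted p = 0.848 with an estimated correlation). Of 66 housekeeping genes 10 rose and 4 fell at 30 min, 25 and 16 at 60 min, 28 and 17 at 120 min and 27 and 14 at 240 min (28 and 15 adjusted over the list alone, camera adjusted p = 0.2, and adjusted p = 0.848 with an estimated correlation), with a median at 30 and 60 min that turned negative with processed signals. Of the 24 of these that encode actin-binding and actin-depolymerizing proteins 7 rose and 8 fell at 240 min, and of the other 42 members 20 rose and 6 fell (median 0.45), a split made after the values had been seen. Of 131 features of microRNA probes 2 rose and 4 fell at 30 min, 24 and 9 at 60 min, 10 and 15 at 120 min and 8 and 23 at 240 min, where 7186, 14032, 14761 and 13378 of all 23622 features were called at these times. A further 286 genes were called in a single direction at all 4 times with no called difference between times, 136 higher and 150 lower, of which 42 changed at least 2-fold at every time. With no dye swap, such a constant ratio cannot be told apart from a dye effect specific to the gene.

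Untreated leaves differed between the slides for genes of jasmonate responses. The untreated level on slide 2 minus that on slide 1 was 2.26 for RERJ1, 2.05 for OPR1, 1.52 for AOS2, 0.97 for MYC2, -3.11 for LIS and -3.77 for the lipoxygenase gene LOX_RCI1. All 4 genes of transcription factors linked to jasmonate stood higher on slide 2 by at least 0.5, as did 5 of 12 genes of jasmonate biosynthesis, where 1 stood lower, and 7 of 16 JAZ genes, where 3 stood lower. Among all genes 1878 stood higher (7.95%) and 1767 lower (7.48%) by as much. These levels come from channels after loess and Aquantile. Over all tested genes the spread between untreated channels was 0.139 to 0.189 for arrays of a slide and 0.416 to 0.444 for arrays of different slides. Some of the named genes moved more within a slide. Their SD over the 4 arrays of slides 1 and 2 was 0.61 and 0.408 for RERJ1, 0.479 and 0.594 for OPR1. It was 0.809 and 0.627 for LOX_RCI1 and 0.343 and 0.124 for LIS. For AOS2 it was 0.0643 and 0.0615, and for MYC2 0.0285 and 0.0406.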
